A study of Mus musculus with 4 samples.

How the data were processed

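RNA of thioglycolate-elicited, adherent mouse peritoneal cells was hybridised as biotin-labelled cRNA to Affymetrix arrays, with 2 arrays for PBS and 2 for TGFb2 (5 ng per the labels' protocols, which give no volume). The values used here are the deposited probe set intensities of the series. They are MAS5 signals, per the submitters' processing notes, which give no version; MAS5 combines the perfect-match and mismatch probes of a probe set into a background-corrected intensity on a linear scale. The deposited intensities ran from 0.1 to 15281 and their 2% trimmed means were equal on the 4 arrays (150.1), so no further scaling was applied. The scanner cell files, detection calls and any filter of the authors are not given in the sources used here. No probe set was therefore known to be present or absent, and precision was limited by the number of arrays.

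Of the 12488 probe sets, 66 are controls and were left out of the tests. Of the others, 10833 carried 1 gene symbol in the platform annotation, 396 several and 1193 none. Symbols were looked up through the gene ID in the table of the GRCm38.p6 assembly, where 10817 were found and 0 changed. Probe sets with several symbols or none were tested but not named. Probe sets whose identifier ends in _f_at, _s_at or _r_at can share probes with related genes or use fewer probes, so the values of gene families such as Gstm1 are less certain.

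Signals were taken to log2(signal + 15), where 15 is 10% of the trimmed mean, so differences on this scale understate the change of dim genes. Probe sets with a mean over all 4 arrays at or above the 40th percentile, a signal of about 24.0, were tested, which left 7453 probe sets and 5639 genes. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), TGFb2 against PBS over all 4 arrays without further terms, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual and 5.6 prior degrees of freedom, and the median standard error of a log2 difference was 0.21. In simulated data with these levels and spreads (20 runs of 200 changed among 7453 probe sets), the fit recovered 39.5% of 2-fold and 92.95% of 4-fold changes. Of its calls, 5.83% were false. The simulated errors were independent and followed the fit's own variance model. These shares therefore do not test whether that model holds for the real arrays.

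Each gene was represented by its tested probe set with the highest mean. The study design, the tests, 38 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 genes with the largest rise and the 10 with the largest fall past the threshold without overlap between groups, up to 2 passing genes per direction of each list (or, where none passed, the 2 with the largest difference), and every tested gene of the list recalled from published work. Gene lists with at least 5 tested members (37 lists) were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. In simulations with 5639 genes, camera found 20 of 20 lists of 20 genes shifted by 0.5 on the log2 scale and called 1 of 600 unshifted lists. The simulated genes varied independently and the lists were drawn at random, so these counts do not test the preset correlation.

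No values were identical between arrays beyond chance ties (52 to 98 of the 12488 probe sets per pair), so every array was kept as a sample. Alternatives covered the pseudocount, normalization between arrays, the filter, the variance model, the replicate number as a block, the set test, the probe sets per gene and leaving out each array in turn. Array or scan dates are not given in the sources used here, so no such batch could be tested. Some listed genes were not analysed here.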

Results

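Gene expression was measured in mouse peritoneal macrophages cultured overnight with transforming growth factor beta 2 (TGFb2) or with the PBS vehicle. The cells were elicited in female BALB/c mice aged 6 to 8 weeks by an intraperitoneal injection of 2 ml of 3% thioglycolate, an irritant that draws macrophages into the peritoneal cavity, and were collected 4 days later. The adherent fraction, which the labels give as over 95% positive for the macrophage surface marker F4/80, was used for RNA. Each group held 2 arrays, named here PBS replicates 1 and 2 and TGFb2 replicates 1 and 2. The labels do not say whether the replicates came from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical. The 12488 probe sets had median signals of 43.5 and 40.6 on the PBS arrays and 45.6 and 40.1 on the TGFb2 arrays. Log2 signals of the tested probe sets correlated at 0.979 between the PBS arrays and at 0.968 between the TGFb2 arrays, and at 0.954 to 0.966 between arrays of different groups.

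The comparison of TGFb2 with PBS addressed which transcripts change when elicited macrophages are exposed to this cytokine, which the series describes as giving the cells tolerogenic properties. Biglycan (Bgn), a matrix proteoglycan, rose from a signal of 84.7 ± 12.5 to 748 ± 180.1 (SD, n = 2 arrays per group, as in all values below), a log2 difference of 2.92 with a standard error of 0.21 (limma, adjusted p = 0.00189). A dimmer probe set of Bgn differed by 0.93 (adjusted p = 0.11). Elastin (Eln), the elastic fibre protein, rose from 74.6 ± 13.01 to 518 ± 10.7, a log2 difference of 2.58 ± 0.18 (SE, adjusted p = 0.00179). Serpinh1, a chaperone of collagen folding, rose from 55.9 ± 13.8 to 278 ± 75.4, and Timp1, an inhibitor of matrix metalloproteinases, rose from 341 ± 151 to 1684 ± 521. Tgfbi, a secreted matrix protein named for its induction by TGF-beta, rose from 40.7 on each PBS array to 227 ± 49.1. Scx, a transcription factor of tendon cells, rose from 22.2 ± 19.5 to 168 ± 59.7, from a PBS mean below the filter level.

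Of the 10 genes that rose most in their brightest probe sets, the other 4 were Cdo1, Tmem37, Htr2b and Fabp7. Outside this ranking, dimmer probe sets of Serpinf1 and Col1a1 rose by 2.81 and 2.72 (limma adjusted p = 0.0175 and 0.00176). That of Serpinf1 had PBS signals of 12.6 and 1.2, below the filter level, so the size of its log2 difference depends on the pseudocount. The brightest probe set of Serpinf1 differed by 0.56 (limma adjusted p = 0.50). The cysteine dioxygenase Cdo1, which degrades cysteine, rose from 19.3 ± 11.3 to 258 ± 83.5. Its PBS mean lies below the filter level, so the size of its log2 difference, 3.00 ± 0.30 (SE), depends on the pseudocount and was 1.99 with 4 times the pseudocount. The membrane protein gene Tmem37 rose from 150.3 ± 4.10 to 872 ± 63.8 (adjusted p = 0.00176), the serotonin receptor Htr2b rose from 58.3 ± 3.75 to 310.2 ± 10.3, and the fatty acid binding protein Fabp7 rose from 418 ± 226 to 1638 ± 14.8. Limma adjusted p for these 10 genes lay between 0.00176 for Tmem37 and 0.0431 for Scx.

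Among the genes that fell, Cdkn1c, an inhibitor of cyclin-dependent kinases, went from a signal of 1248 ± 6.29 to 158 ± 40.7, a log2 difference of -2.89 ± 0.20 (SE, adjusted p = 0.00176). The chemokine Cxcl5 fell from 344 ± 223 to 51.3 ± 14.1, and Cxcl2, a chemoattractant of neutrophils, fell from 90.0 ± 2.40 to 25.8 ± 4.17. The interleukin-1 receptor antagonist Il1rn fell from 2156 ± 264 to 836 ± 178, a log2 difference of -1.36 ± 0.18. Cd200, a ligand of an inhibitory myeloid receptor, fell from 379 ± 31.7 to 147 ± 22.8, and the semaphorin Sema4d fell from 939 ± 23.5 to 346 ± 43.7. Dio2, which activates thyroid hormone, fell from 356 ± 133 to 81.6 ± 13.4, and the interferon-induced transmembrane family member Ifitm6 fell from 146 ± 33.5 to 44.2 ± 5.73. Decorin (Dcn), a matrix proteoglycan of fibroblasts, fell from 939 ± 271 to 288 ± 44.0, opposite in direction to biglycan. The ubiquitin ligase gene Arih1 fell by 1.71 on the log2 scale, while its other tested probe set differed by -0.21 (adjusted p = 0.74). Limma adjusted p for the 10 genes that fell most in their brightest probe sets lay between 0.00176 for Cdkn1c and 0.0478 for Cxcl5.

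**Figure D1:**
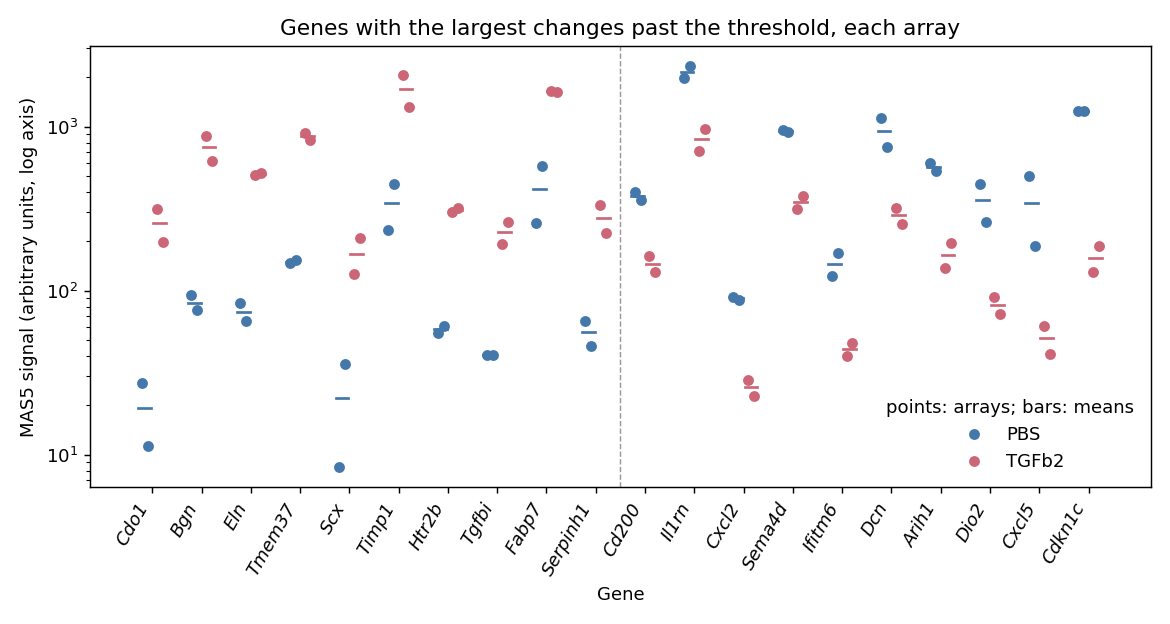
MAS5 signal in arbitrary units (vertical log axis) of the 10 genes that rose most and the 10 that fell most past the threshold (horizontal axis). Genes were ranked by their brightest probe sets, and there is a point for each of the 4 arrays and a bar for each group mean. Arrays of the groups do not overlap for any of these genes, with biglycan going from 84.7 to 748 and Cdkn1c from 1248 to 158.

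Over all 7453 tested probe sets, 88 passed an adjusted p of 0.05 in limma, of which 61 were higher and 27 lower with TGFb2, and 81 of them represented 79 named genes. A change of at least 2-fold with no overlap between the groups was found for 171 probe sets, 107 higher and 64 lower. Groups without overlap, at any size of change, made up 42.8% of the tested probe sets, where chance gives 33.3%. With 2 arrays per group the number of calls depended on each array. It was 42 without PBS replicate 1, 34 without PBS replicate 2, 11 without TGFb2 replicate 1 and 25 without TGFb2 replicate 2, where the lone array was assumed to vary like the other group, and it was 57 without a pseudocount, 16 without the intensity trend of the variance and 6 when dim probe sets were not filtered out. Of the 36 named genes past the threshold, 20 and 21 passed without PBS replicates 1 and 2, and 6 and 15 without TGFb2 replicates 1 and 2, while Bgn, Eln, Tmem37, Htr2b and Cdkn1c passed under each of 14 alternatives.

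Genes of TGF-beta signalling and its targets were higher as a group. Of 17 tested members, each counted here and in all lists below by its brightest probe set alone, 2 rose, 0 fell and 15 did not pass over all probe sets tested, while 9 rose when adjusted over the list alone. Tgfbi is given above, and Id3, an inhibitor of helix-loop-helix transcription factors, rose from 27.3 ± 3.18 to 145 ± 36.6, a log2 difference of 1.91 ± 0.23 (SE) that was 1.22 with 4 times the pseudocount. The median member differed by 0.64 on the log2 scale (limma camera with a preset correlation, adjusted p = 2.19e-05), and by 0.20 with the filter at the 60th percentile. The call was lost with an estimated correlation (adjusted p = 0.57 with an estimated correlation), where the test has only 2 degrees of freedom. None of the 8 lists called by camera kept its call in that test, and their adjusted p in it lay between 0.57 and 0.70.

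Extracellular matrix and protease genes gave the smallest list p. Of 20 tested members, 5 rose, 0 fell and 15 did not pass, and 9 rose and 1 fell when adjusted over the list alone. Timp1 and Tgfbi, of this list, are given above. The median difference was 0.59 (camera, adjusted p = 1.46e-07, and adjusted p = 0.57 with an estimated correlation), and fry, which tests only the list's own genes, gave an adjusted p of 0.00288. For the other 7 called lists fry gave an adjusted p between 0.082 and 0.18. Markers of fibroblasts and mesothelium, the other adherent cells of the peritoneum, moved with the treatment in both directions. Of 12 tested, 3 rose, 1 fell and 8 did not pass, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.33). Fibulin 2 (Fbln2) rose from 78.4 ± 14.2 to 259 ± 82.7 and the collagen chain Col5a2 from 35.1 ± 12.7 to 117 ± 3.18, whereas decorin fell as given above. Probe sets of collagen I, singled out after their values were seen, disagreed in size. Those of Col1a1 differed by 1.29 and 2.72, both past the threshold, and those of Col1a2 by 0.16 (adjusted p = 0.78) and 1.86 (adjusted p = 0.0175).

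Integrin and cytoskeletal adhesion genes were higher as a group, with 2 of 21 tested members risen, 0 fallen and 19 not past, and 6 risen when adjusted over the list alone. The actin-binding protein transgelin (Tagln) rose from 25.5 ± 13.6 to 145 ± 64.5 and the leukocyte integrin chain Itgal from 18.7 ± 5.23 to 117 ± 31.6. The median difference was 0.18 (camera, adjusted p = 0.00289, and adjusted p = 0.70 with an estimated correlation), and 0.06 to 0.26 over the alternatives. The call was also lost without TGFb2 replicate 2 (adjusted p = 0.099) and with the filter at the 60th percentile (0.066), in a range over all alternatives of 0.000226 to 0.70.

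Chemokine genes were lower as a group. Of 15 tested members, 0 rose, 3 fell and 12 did not pass, and 9 fell when adjusted over the list alone. The falls of Cxcl5 and Cxcl2 are given above. The median difference was -0.84 (camera, adjusted p = 0.000359, and adjusted p = 0.57 with an estimated correlation). It depended on the choices made, from -1.13 without a pseudocount to -0.51 with 4 times the pseudocount and -0.24 without the filter on dim probe sets. Of 9 tested receptors for chemokines and other chemoattractants, 0 passed, with 1 fallen when adjusted over the list alone (camera adjusted p = 0.83). The chemokine receptor Ccr1 had signals of 645 ± 144 and 328 ± 101 (adjusted p = 0.15) and the formyl peptide receptor Fpr2 of 54.8 ± 46.3 and 10.5 ± 4.38 (adjusted p = 0.35).

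Of 12 tested complement genes, 3 rose, 0 fell and 9 did not pass, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.075). The 3 were the chains of C1q, the recognition component of the classical pathway, of which C1qb rose from 63.1 ± 7.85 to 234 ± 40.5 and C1qa from 167 ± 5.66 to 468 ± 90.5. A second probe set of C1qb differed by -0.24 (adjusted p = 0.77). Lysosomal genes shifted upwards by a median of 0.19, with 2 of 27 risen, 0 fallen and 25 not past, and 5 risen when adjusted over the list alone (camera, adjusted p = 0.000359, and adjusted p = 0.70 with an estimated correlation). The protease cathepsin H (Ctsh) rose from 565 ± 20.6 to 1188 ± 157 and the lysosomal mannosidase Man2b1 from 1737 ± 298 to 3498 ± 92.4, while a dimmer probe set of Man2b1 differed by 0.12 (adjusted p = 0.92). The lysosomal list did not pass after quantile normalization of the arrays (adjusted p = 0.087), in a range over all alternatives of 6.35e-05 to 0.70, and its median ran from 0.09 to 0.27.

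Phagocytic, scavenger and Fc receptors shifted upwards by a median of 0.23, with 1 of 19 risen, 1 fallen and 17 not past, and 5 risen and 1 fallen when adjusted over the list alone (camera, adjusted p = 0.0144, and adjusted p = 0.57 with an estimated correlation). The inhibitory Fc receptor Fcgr2b rose from 379 ± 9.12 to 701 ± 12.6, and the scavenger receptor Cd36 fell from 221 ± 19.2 to 94.8 ± 2.19. Macrophage identity genes shifted by a median of 0.17, with 0 of 16 past, 5 risen when adjusted over the list alone (camera, adjusted p = 0.0102, and adjusted p = 0.57 with an estimated correlation) and no call after quantile normalization (adjusted p = 0.101) or cyclic loess (0.066). Fcgr1, the high-affinity Fc receptor, had signals of 169.6 ± 11.4 and 398 ± 116 (adjusted p = 0.066). The efferocytosis receptor Mertk had signals of 42.3 ± 6.93 and 82.9 ± 3.11 (adjusted p = 0.18). Fcgr1, Mertk, Cd14, Cd68 and Msr1 are on both the receptor list and the macrophage identity list, so these lists are not independent. Without TGFb2 replicate 2 neither list passed (adjusted p = 0.055 for the receptors and 0.12 for macrophage identity). The receptors also did not pass without TGFb2 replicate 1 (0.066) or with the filter at the 60th percentile (0.066). Over all alternatives adjusted p ran from 0.00777 to 0.57 for the receptors and from 0.00464 to 0.57 for macrophage identity, and the medians from 0.13 to 0.27 and from 0.11 to 0.24.

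Genes of tissue macrophages that depend on TGF-beta shifted upwards by a median of 0.49, with 1 of 10 risen, 0 fallen and 9 not past, and 4 risen when adjusted over the list alone (camera, adjusted p = 0.00867, and adjusted p = 0.57 with an estimated correlation). The member that passed was the matrix protein gene Sparc, which rose from 65.9 ± 9.83 to 218 ± 31.7, and the list did not pass without TGFb2 replicate 2 (adjusted p = 0.099) or with the filter at the 60th percentile (0.066), in a range over all alternatives of 0.00421 to 0.57. Its median ran from 0.29 to 0.56. Sparc is also on the matrix list and is among the members that rose there, so these lists are not independent. Of 5 tested genes of resident peritoneal macrophages, Fabp7 rose and the other 4 did not pass, with 1 risen and 1 fallen when adjusted over the list alone (camera adjusted p = 0.73). Of 14 genes of cholesterol efflux and lipid handling, 1 rose and 13 did not pass, and 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.35). The member that passed was the lipoprotein component Apoc2, from 55.9 ± 20.4 to 232 ± 11.0.

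**Figure D2:**
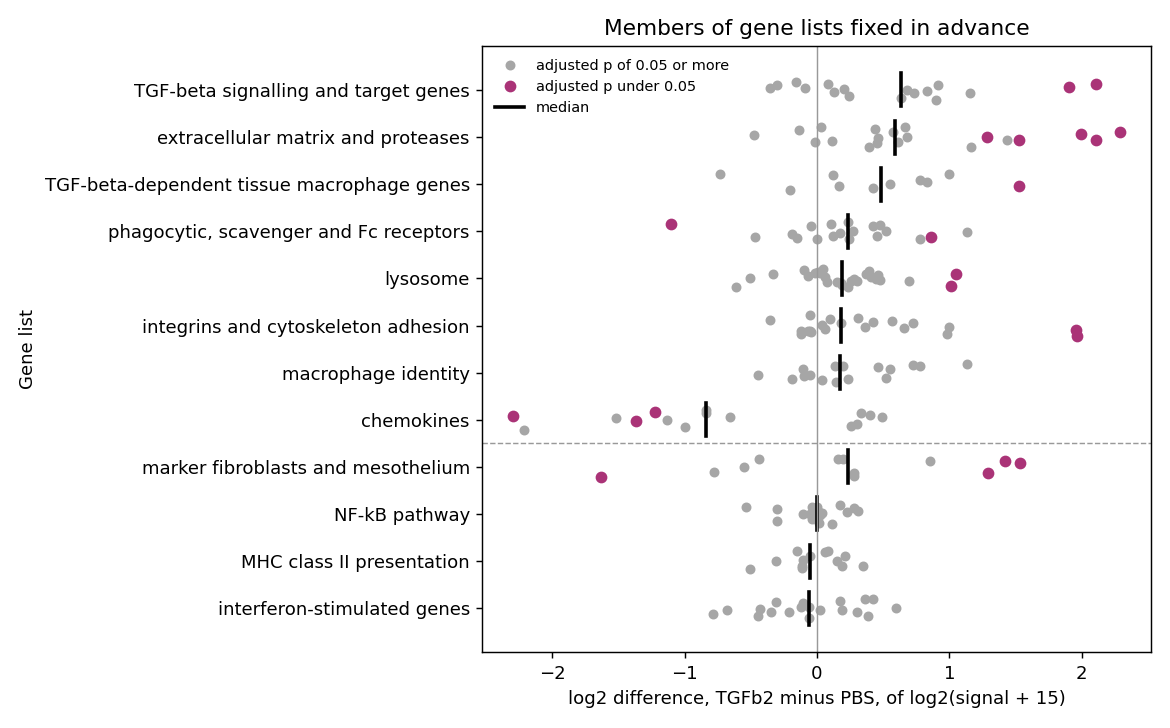
Log2 difference between TGFb2 and PBS (horizontal axis, of log2 signal plus 15) of each tested member of the 8 lists that passed camera with a preset correlation, above the dashed line, and of 4 lists that did not, below it (vertical axis, lists). Coloured points passed the threshold and black bars are medians, which lie at 0.59 for the matrix list, -0.84 for the chemokines and 0.00 for the NF-kB pathway.

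Genes of inflammatory signalling and antigen presentation showed few changes past the threshold, and where 0 members of a list are given as past here, 0 passed when adjusted over the list alone too unless stated. Of 18 pro-inflammatory cytokines and effectors on the array, 11 lay below the level filter, among them Il1b, Il6, Ptgs2 and Nos2. These were not tested, and of the 7 tested 0 passed (camera adjusted p = 0.82). Interleukin 1 alpha (Il1a) had signals of 423 ± 185 and 278 ± 38.8 (adjusted p = 0.55), and Csf3 of 56.8 ± 5.52 and 87.8 ± 37.9 (adjusted p = 0.59). Of 15 anti-inflammatory and inhibitory genes, only Il1rn passed in its brightest probe set, and 4 fell when adjusted over the list alone (camera adjusted p = 0.57). Of 3 probe sets of annexin A1 (Anxa1) on that list, singled out after their values were seen, 2 fell by 0.96 and 1.09, and the brightest differed by -0.63 (adjusted p = 0.058). Of 18 genes of the NF-kB pathway, 0 passed (camera adjusted p = 0.94), with Nfkbie at 64.0 ± 14.2 and 39.0 ± 4.03 (adjusted p = 0.44) and Myd88 at 160.1 ± 14.4 and 203 ± 34.2 (adjusted p = 0.61). Of 9 Toll-like receptor signalling genes, 0 passed (camera adjusted p = 0.83), with Cd180 at 84.3 ± 20.5 and 61.4 ± 9.19 (adjusted p = 0.61). Of 28 interferon-stimulated genes on the array, 9 lay below the level filter. Of the 19 tested, 0 passed (camera adjusted p = 0.82), with Usp18 at 129 ± 20.4 and 69.3 ± 20.4 (adjusted p = 0.22). Gbp2 was at 122 ± 62.6 and 67.4 ± 20.4 (adjusted p = 0.50).

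Of 13 genes of MHC class II presentation and 14 of MHC class I presentation, 0 passed in either list (camera adjusted p = 0.94 and 0.62). Legumain (Lgmn) had signals of 1931 ± 550.3 and 1329 ± 88.0 (adjusted p = 0.38), H2-DMb1 of 61.6 ± 16.9 and 81.6 ± 11.2 (adjusted p = 0.63), Cd1d1 of 46.7 ± 12.8 and 65.8 ± 21.99 (adjusted p = 0.67) and the peptide transporter Tap2 of 44.7 ± 4.10 and 60.3 ± 19.5 (adjusted p = 0.70). Among 9 costimulatory and adhesion ligands, Cd24a, a surface glycoprotein, rose from 1065 ± 53.1 to 2129 ± 143, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.82). Of 10 genes of alternative activation, 0 passed, while 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.74). Arginase 1 (Arg1) had signals of 358 ± 99.6 and 873 ± 228 (adjusted p = 0.066), and the chemokine Ccl22 of 50.5 ± 32.2 and 15.8 ± 1.13 (adjusted p = 0.36).

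Genes previously associated with TGF-beta-treated antigen presenting cells formed a separate list, recalled from published work on this cell model. Part of that work may rest on these arrays, so the list is not independent evidence of a direction. Of 11 tested members, 0 rose, 2 fell (Cxcl2 and Cd36) and 9 did not pass, and 1 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.82). Tgfb3 had signals of 43.9 ± 13.3 and 95.7 ± 18.6 (adjusted p = 0.18), the tumour necrosis factor receptor Tnfrsf1b of 906 ± 84.4 and 1199.7 ± 261 (adjusted p = 0.47), and the chemokine Ccl3 of 250.0 ± 62.8 and 131 ± 0.99 (adjusted p = 0.15). The NF-kB inhibitor Nfkbia differed by 0.18 ± 0.21 (SE, adjusted p = 0.80), Cd40 by 0.27 ± 0.27 (adjusted p = 0.77), Tnf by 0.25 ± 0.29 (adjusted p = 0.79), Tgfb1 by -0.16 ± 0.22 (adjusted p = 0.83) and Cd47 by 0.04 ± 0.21 (adjusted p = 0.97) on the log2 scale. All of these but Cd40, which ran from 0.11 to 0.43, changed sign under at least 1 alternative. Second probe sets of Nfkbia and Cd47 had the opposite sign, at -0.11 (adjusted p = 0.92) and -0.14 (adjusted p = 0.82). Tgfb2, Il10, Il12a and Il12b lay below the level filter, with signals of at most 24.1, 11.8, 5.6 and 49.3 on any array, and were not tested. One more listed gene was not analysed here.

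Of the 8 lists of metabolism, stress and growth in this paragraph, 1 gene passed. The glutathione transferase Gstm1 fell from 3435 ± 276 to 2039.8 ± 194, and its second probe set had the opposite sign (0.18, adjusted p = 0.90). It was the only one of 20 genes of oxidative stress and metal binding to pass, while 1 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.056). None of 20 genes of cholesterol and fatty acid synthesis, 17 of glycolysis and hypoxia, 24 of oxidative phosphorylation, 27 of the cell cycle, 18 immediate early genes, 21 of heat shock and ER stress or 17 of apoptosis passed, with camera adjusted p between 0.33 and 0.94. Adjusted over the list alone, 1 glycolysis gene and 2 immediate early genes fell, and 0 passed in the other 5 of these lists. Dhcr7 differed by 0.65, Mvd by 0.57, Aldoc by 0.70, Hk1 by -0.61, Sdha by -0.47, Ndufa1 by -0.33, Pcna by -0.80, Ccna2 by -0.63, Dusp1 by -1.05, Btg2 by -0.78, Hspd1 by -1.17, Atf5 by 0.51, Bcl2l11 by 0.59 and Bcl2l1 by -0.41 on the log2 scale, with limma adjusted p between 0.079 for Dusp1 and 0.67 for Ndufa1. A second probe set of Hspd1 differed by 0.57, in the opposite direction. Over the alternatives Hspd1 ran from -1.70 to -0.30, Ndufa1 from -0.56 to -0.11, Mvd from 0.31 to 0.83, Aldoc from 0.42 to 0.90, Sdha from -0.65 to -0.29 and Btg2 from -1.06 to -0.49.

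Markers of blood and immune cells that an adherent exudate could also hold showed 2 genes past the threshold in their brightest probe sets, S100a8 and Cd24a. Of 17 neutrophil markers on the array, 11 lay below the level filter and 6 were tested, of which S100a8 rose from 169.8 ± 58.1 to 615 ± 90.9 and 5 did not pass (camera adjusted p = 0.29; 1 risen when adjusted over the list alone). Dimmer probe sets of 2 more markers, singled out after their values were seen, did pass. The granulocyte colony-stimulating factor receptor Csf3r, a neutrophil marker, rose by 1.75 in 1 of its 3 tested probe sets and differed by -0.15 and 0.01 in the others. The T and NK cell kinase Zap70 rose in a dim probe set, with signals of 9.9 and 8.1 on the PBS arrays and 57.2 and 51.6 on the TGFb2 arrays (adjusted p = 0.0470), and differed by 0.19 in a brighter one (adjusted p = 0.90). Of 9 dendritic cell markers only Cd24a passed (camera adjusted p = 0.94; 1 risen and 1 fallen when adjusted over the list alone). Of 4 tested T and NK cell markers, 9 B cell markers, 5 eosinophil and mast cell markers and 6 erythrocyte, platelet and endothelial markers, 0 passed in the brightest probe sets, over all probe sets or when adjusted over the list alone (camera adjusted p of 0.82, 0.82 and 0.56 for the last 3). The largest differences in the brightest probe sets were -0.31 for Gzmb, -0.23 for Cd4, -0.61 for Ighm, 0.35 for Cd22, 0.76 for Cpa3, 0.43 for Tpsb2, 0.75 for Pecam1 and 0.73 for Kdr. These sizes depended on the choices made and on single arrays, with Pecam1 running from 0.07 to 1.44, Cpa3 from 0.37 to 1.20 and Cd4 from -0.76 to 0.31 over the alternatives. Of 15 housekeeping genes 0 passed (camera adjusted p = 0.94). The actin gene Actb, at 53.6 ± 22.8 and 223 ± 241 in its brighter single-gene probe set (adjusted p = 0.55), had the largest difference among them. Its signals were 52.1 and 393.2 on the TGFb2 arrays, so this difference rests on TGFb2 replicate 2. The actin control probe sets had signals of 8809 to 13084, so this dim probe set is a doubtful measure of actin. In 9 of the 37 tested lists, none of them called, the median, the mean and the direction of the camera test differed in sign.

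The log2 ratio of the 3' to the 5' control probe set, which rises when RNA is degraded or poorly copied, was 0.16 and 0.16 for actin on the PBS arrays and 0.06 and 0.11 on the TGFb2 arrays. For Gapdh it was -0.32 and -0.26 with PBS and -0.50 and -0.36 with TGFb2. For the transferrin receptor it was 1.16 and 2.12 with PBS and 1.15 and 2.03 with TGFb2. For 18S ribosomal RNA it was 1.02 and 1.85 with PBS and 1.14 and 1.69 with TGFb2. The ratios of the transferrin receptor and 18S were thus higher on replicate 2 in both groups. The 3' control probe set of 18S ribosomal RNA had signals of 248 and 1066 on the PBS arrays and of 196 and 261 on the TGFb2 arrays, so PBS replicate 2 stood apart in this signal.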

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

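The tests of explanations below were chosen after the results were seen, although quantile normalization and cyclic loess were alternatives planned before. Outside the tests, 8 of 22 mouse control probe sets above the level filter were higher on both TGFb2 arrays than on both PBS arrays. Another 4 were lower on both TGFb2 arrays. Of the tested probe sets, 42.8% had no overlap between groups in either direction, where chance gives 33.3%. All 8 but the control for B2 repeats are probe sets of actin or Gapdh, so they are not separate genes. The log2 differences of the actin controls were 0.27 (3'), 0.34 (5') and 0.23 (middle), and those of the Gapdh controls were 0.22 (3'), 0.36 (5') and 0.22 (middle). The sense-strand Gapdh 3' control differed by 0.61 at dim signals of 60.5 ± 12.9 and 101 ± 27.8. The control for B2 repeats differed by 0.23, with signals of 6836 and 6854 on the PBS arrays and 9321 and 6913 on the TGFb2 arrays. Its difference thus rests on TGFb2 replicate 1. No adjusted p was computed for these controls.

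The first pattern is the rise of matrix genes with TGFb2. Scaling of the arrays accounts poorly for it, since the matrix list had an adjusted p of at most 2.24e-07 under quantile normalization and cyclic loess, although its call was lost with an estimated correlation (adjusted p = 0.57). A larger share of fibroblasts or mesothelial cells in the TGFb2 wells, where the labels give over 95% F4/80-positive cells, stays open. Of 6 abundant markers, none shared with the matrix list, only 1 (decorin, which fell by 1.63) lay over 2 standard errors below the 0.59 median of that list. The most favourable probe set of each marker was used. All 6 but Pdgfra (0.25 ± 0.24, SE) encode matrix proteins themselves. The comparison therefore cannot separate more of these cells from a rise of matrix genes. A response to TGFb2 within the wells may explain the rise as well. The 16 TGF-beta genes not in the matrix list were shifted by a median of 0.44 (camera p = 2.24e-05, and p = 0.045 with an estimated correlation). They are the TGF-beta list called above without Tgfbi, so most of this shift was known before the test was chosen. It also cannot separate a response from a larger share of fibroblasts. Whether macrophages or fibroblast-like cells carried the matrix transcripts was not tested.

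The second pattern is the fall of chemokine genes, with a median of -0.84 that ran from -1.13 to -0.24 over the alternatives and a call that was lost with an estimated correlation (adjusted p = 0.57). Fewer macrophages among the adherent cells would lower macrophage transcripts alike, but 15 of 16 macrophage identity genes lay over 2 standard errors above that median, and the lowest count under any alternative was 10 of 16, without the filter, where the median was -0.24. A fall of NF-kB driven transcription as large as that of the chemokines was not settled over all settings. Of 10 genes under its control 9 lay over 2 standard errors above the median of -0.84, which argues against it for the tested chemokines. Without the filter only 1 of the 10 lay over 2 standard errors above the chemokine median. That median was itself -0.24 there, since dim chemokines entered the list, so this setting cannot decide. The 10 genes had a median of -0.04 in the main fit and without the filter. TGFb2 against PBS is the only difference between the groups that the labels give. By what route, or in which cells, the chemokine genes fell was not tested.

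The number of calls cannot be set against chance by regrouping, since 4 arrays allow only 3 splits, too few for a share under 0.05. The real split called 88 probe sets, as many were found in 1 of the 3 splits, and the highest other split called 0.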

How the results depend on the processing

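The count of 88 probe sets past the threshold fell to 57 without a pseudocount, to 16 without the intensity trend and to 6 without the filter on dim probe sets, and rose to 320 with the replicate number as a block, which shared all 88. Leaving out an array gave 11 to 42. It lay between 74 and 102 under the other alternatives, of which quantile normalization and cyclic loess shared 78 and 86 calls with the 88. The count of 171 probe sets changed at least 2-fold without overlap became 280 without a pseudocount, 64 with 4 times the pseudocount and 90 with the filter at the 60th percentile, and 216 to 278 without an array. The count of 8 gene lists became 5 with the filter at the 60th percentile, 1 with fry (the matrix list) and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05, and 4 to 11 without an array. The cause of these shifts was not tested, beyond the 2 degrees of freedom of the estimated correlation. Robust variances were not run for lists, which camera does not offer. The 36 named genes past the threshold kept their direction under every alternative that tested them. Of these, 30 passed without a pseudocount, 8 without the trend, 5 without the filter, and 6 to 21 without an array. With the block all 36 passed, and so did 12 named genes that had not: Ccr1, Usp18, Arg1, Hk1, Pcna, Dusp1, Btg2, Hspd1, Fcgr1, Actb, Tgfb3 and Ccl3. Signs turned only in named genes that had not passed. Cd47 was -0.051 with the mean of its probe sets, and leaving out an array in turn gave -0.21 to 0.29 for Cd47, -0.76 to 0.31 for Cd4, -0.088 to 0.44 for Nfkbia, -0.20 to 0.70 for Tnf and -0.49 to 0.16 for Tgfb1. The labels give replicates the same numbers but no shared origin. Deviations of same-numbered arrays correlated at 0.15, with 2 pairs only, and all 9 hybridisation spike-in controls were brighter on replicate 1 in each group (median log2 difference 0.75 with PBS and 0.57 with TGFb2), which is a hint from the data and not the design. A split of the arrays by number called 0 probe sets past the limma threshold and 292 at an unadjusted p under 0.05, against 867 for the real split.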

Other observations

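Another 43 named genes passed the threshold outside the rule for named genes, 33 higher and 10 lower with TGFb2, and those given here were chosen after their values were seen. Among those that rose were the LIM protein Csrp2, by 1.66 on the log2 scale, the collagen VI chain Col6a3, by 1.37, the plasminogen activator Plau, by 1.29, and the serum and glucocorticoid regulated kinase Sgk1, by 0.75, from signals of 1656 and 1819 on the PBS arrays. The third C1q chain, C1qc, rose by 1.13. Another 3 rose from PBS means below the filter level, where the size of a log2 difference depends on the pseudocount. Tenascin C (Tnc), a matrix glycoprotein, had signals of 24.6 and 9.1 with PBS and 143.2 and 84.1 with TGFb2. Lysyl oxidase (Lox), which crosslinks collagen and elastin, had 4.1 and 7.4 against 74.9 and 60.8, and the sphingosine kinase Sphk1 had 4.0 and 9.8 against 64.2 and 66.7. A second probe set of Lox had 21.8 and 17.2 against 40.1 and 25.2 (limma adjusted p = 0.62). Among those that fell were the chemokine Ccl6, by 1.23, the vesicle fusion genes Vamp4 and Napa, by 1.18 and 1.01, the creatine kinase Ckb, by 0.96, and the monoamine oxidase Maoa, by 0.91. A dimmer probe set of Vamp4 differed by -0.23 (limma adjusted p = 0.72).

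TGF-beta target genes below the level filter were not tested in the report. In the fit without the filter, Skil, which restrains Smad signalling, had signals of 8.2 and 6.3 with PBS and 51.6 and 38.1 with TGFb2 (limma adjusted p = 0.18). Ccn2, a matricellular protein, had 2.1 and 1.2 against 72.8 and 24.4 (adjusted p = 0.24), and Id1 had 5.0 and 6.7 against 38.9 and 25.0 (adjusted p = 0.24). Of the 9 members below the filter, 6 were higher on both TGFb2 arrays than on both PBS arrays, a pattern shown by 21.9% of all probe sets below the filter. None of the 9 passed the threshold.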
